A study of Rattus norvegicus with 54 samples.

How the data were processed

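RNA from rat fetal gubernaculum, the cord-like structure that guides testicular descent, and from fetal testis was measured on 54 one-colour Affymetrix arrays. LE/wt is the wildtype strain of the series and LE/orl its cryptorchid strain. Of the arrays, 34 were hybridised with gubernaculum RNA in 9 groups and 20 with testis RNA in 4 groups. Per the labels, the lower part of each fetus was kept in RNAlater before dissection, and RNA was isolated with a spin-column kit and treated with DNase. Gubernaculum RNA was amplified with a labelling protocol of 2 cycles and testis RNA with a protocol of 1 cycle, so levels were not compared between tissues. Each array held the organ of 1 fetus, and in females both sides of a fetus were combined.

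The authors' value table holds log2 expression values made with GCRMA, per the submitters' processing notes. Values ran from 0.793 to 16.2. Array medians lay between 4.93 and 5.20 in gubernaculum and between 4.78 and 4.86 in testis, and the 75th percentiles between 8.04 and 8.27 and between 7.17 and 7.28. Which arrays the authors normalised together is not given in the sources used here. The authors also deposited 3 lists of selected probe sets with group means on a linear intensity scale. These means were recomputed from the log2 values and matched within 0.51 intensity units for 3589 of 3589 probe sets of the gubernaculum list. For LE/orl at GD18 and GD19 they matched only when GD18 replicate A and GD19 replicate D were left out. With both arrays in, 38 and 50 of the 3589 matched. Per the deposited methods text, the authors selected probe sets with limma in affylmGUI and with an ANOVA in GeneSpring, with a mean expression minimum. Their tests were not rerun here.

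The table has 15923 probe sets, of which 57 controls were kept out of the tests. Gene names came from the authors' lists alone, which name probe sets by an annotation of NetAffx. Of 3922 listed probe sets, 3008 carried 1 symbol, 165 several and 749 none, and the remaining 11952 are unnamed here. A name was given only through a probe set with 1 symbol, for 2844 different genes. Symbols were set against the gene table of the rat assembly GRCr8: 2064 were current, 707 were updated through a synonym and 237 were kept as listed. Every named gene was therefore selected by the authors on these arrays, so the direction of a gene list made of such genes is not independent evidence. Genes of wide interest for this tissue, such as those of Insl3 and its receptor, were not among the names and were not analysed here. A few genes that met the naming rule are not reported here.

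Each tissue was fitted on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), with all groups of the tissue in 1 fit and no covariate. Each named gene was represented by the probe set with the highest mean, beside every unnamed probe set. Features needed a log2 value of at least 5 in at least 3 gubernaculum arrays or 5 testis arrays. This left 8711 features in gubernaculum, 2821 of them named, with 25 residual degrees of freedom, and 7878 in testis, 2564 of them named, with 16. P-values were adjusted by Benjamini-Hochberg within each contrast, and a feature was called at an adjusted p under 0.05. Strain differences are LE/orl minus LE/wt, sex differences male minus female and day differences later minus earlier day. The change of the strain difference with day was tested by an F test over the 3 gubernaculum days and by 1 contrast in testis. For genes with another named probe set passing the minimum (146 in gubernaculum, 123 in testis) both were fitted. Where both were called, they pointed opposite ways for 8 of 79 genes at GD18 between strains, 12 of 55 between the sexes and 2 of 25 in testis at GD17.

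Groups, tests, most alternatives, 24 gene lists and the rule for naming genes were set before the data were examined. The muscle and cytoskeleton lists are general, but it was known when they were made that a publication on this strain deals with such genes. The rule took named genes past the threshold whose compared groups did not overlap: the 8 highest and 8 lowest log2 fold changes in the mean strain, sex and LE/wt day contrasts, 4 and 4 in the others, and the 6 lowest p-values for each change with day. It added up to 3 members of each list with the lowest p-values, whether or not their groups overlapped, and overlap is stated where such a gene is printed. Lists were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, against the other named genes, and again with an estimated correlation. Of 135 list tests, 32 were called with the preset and 10 with the estimated correlation, and these 10 were among the 32. Lists for cartilage and bone, epithelium and mesothelium, adrenal and kidney, and X or Y linkage had no tested member in either tissue.

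Alternatives were no minimum signal, a stricter minimum log2 value of 7, all named probe sets, only the groups compared, array weights, a trended and robust prior, quantile normalisation, median centring, the replicate letter as a block and leaving out each array. Added after seeing the data were leaving out the 2 LE/orl arrays that the authors had left out, the 5′ to 3′ index as a covariate, and the mean of the poly-A spikes as a covariate in gubernaculum. The 5′ to 3′ index is the mean over beta-actin and GAPDH of the log2 value of the 5′ control probe set minus that of the 3′ one. The poly-A spike mean averages the log2 values of the 3′ probe sets of the bacterial spikes Dap, Lys and Phe. Replicate letters mark the same fetus only for the left and right gubernaculum of a strain at GD20, per the labels. For that contrast the fetus was also fitted as a block, with a consensus correlation of 0.405.

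The fit was tested on simulated data with 200 changed features in each of 5 runs. At a 2-fold change it recovered 55.2% of changed features at GD18, 63.9% at GD19, 63.3% at GD20 left, 43.9% at GD20 right and 29.6% for the change with day in gubernaculum. It recovered 63.3% for sex, 61.8% and 60.3% for the days of LE/wt and LE/orl, and 83.0% for the sides. In testis it recovered 97.3% at GD17, 96.7% at GD19 and 91.0% for the change with day. In lists of 20 genes raised by 0.5 on the log2 scale in the testis GD17 design, camera called 100 of 100, and 7 of 100 left alone. The simulated genes varied independently, whereas real lists were correlated, with an estimate of 0.508 for the sarcomere list in gubernaculum. These rates therefore do not carry over to the lists tested. The number of arrays limits the precision of each value. No pair of arrays held identical values.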

Results

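Transcript levels were measured in the gubernaculum and testis of LE/wt rat fetuses and of LE/orl fetuses, a strain with inherited cryptorchidism. Male gubernacula were taken on the left side at GD18, GD19 and GD20 with n = 4 per strain and day. At GD20 right gubernacula were added with n = 3 per strain, and female LE/wt gubernacula at GD18 with n = 4. Left testes were taken at GD17 and GD19 with n = 5 per strain and day. Replicates were separate fetuses, and left and right gubernacula of the same strain and letter at GD20 came from the same fetus. Replicate arrays correlated at r = 0.868 or more across features in gubernaculum and at 0.978 or more in testis. Control probe sets for beta-actin and GAPDH showed that 13 of the 15 LE/orl gubernaculum arrays had a weaker 5′ signal, with a 5′ to 3′ index between −7.23 and −6.07. LE/orl GD18 replicate A and GD19 replicate D, the arrays that the authors left out of their means, had −4.16 and −4.32. The 19 LE/wt gubernaculum arrays lay between −4.73 and −3.46, so this measure of RNA or labelling quality differed with strain. Of 603 pairs of a named gene and a comparison, 130 had a group mean under the minimum log2 signal of 5, and the size of such a difference is uncertain because at least one level is near background. Among the genes named here they include Slc3a1, Ptprj, Cpt1a, Tk1, Id3, Selenow, Selenom, Cyba, Acta2, C1qc, Uchl1 and Cdh5 between the strains in gubernaculum, Cited1, Aftph, Pls3, Myf6, Acta2, Nr2f2, Cdh5 and Scd between the sexes, Pla1a, Scd, C1qc and Cdh5 between the days of LE/wt, Bmyc in the change with day, and Slc3a1, Zp2, Igfbp5, Lama2, Scd and Igfbpl1 in testis. Jag1 between the strains on the left at GD20 also had a group mean under this minimum. For Slc3a1 in testis at GD17 both strains lay under it.

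**Figure D1:**
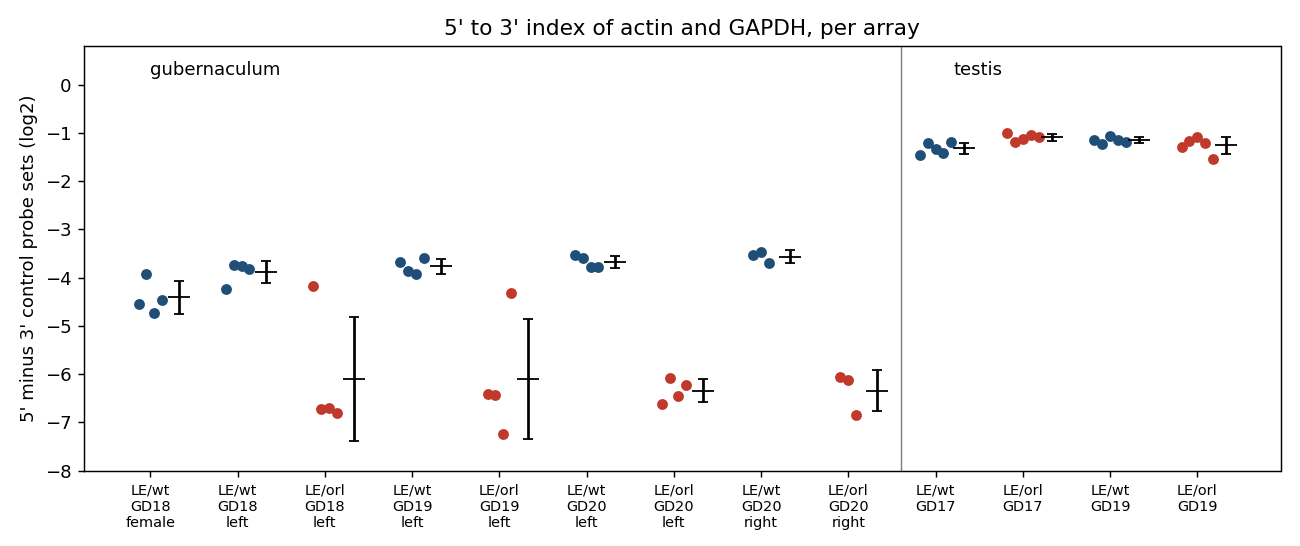
The 5′ to 3′ index of the actin and GAPDH control probe sets (log2 value at the 5′ end minus that at the 3′ end, vertical axis) is shown for each array, with arrays grouped by tissue, strain, day, sex and side, and bars giving the group mean ± SD. LE/orl gubernacula averaged −6.10 ± 1.29 at GD18 and −6.10 ± 1.24 at GD19 against −3.89 ± 0.24 and −3.76 ± 0.16 in LE/wt, while testis arrays lay between −1.53 and −0.999.

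The strain comparison in gubernaculum asked which transcripts differ in the cryptorchid strain around the time of descent. At GD18 and GD19, several genes of differentiated striated muscle were lower in LE/orl left gubernaculum, although their lists as a whole were not called. They included Myl3, a slow myosin light chain, Myoz2, a Z-disc protein, and Sln, a small regulator of the sarcoplasmic calcium pump. Several subunits of the respiratory chain were lower too, among them Cox4i1 and the ATP synthase subunit Atp5mc1. Higher in LE/orl were Slc3a1, which forms part of a cystine and basic amino acid transporter, and Sfrp2 and Spry1, secreted and intracellular antagonists of Wnt and Fgf signalling. The muscle transcription factor Mef2c was higher in LE/orl, opposite to the contractile genes.

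Myl3 differed by −2.05 (log2, SE 0.39, adjusted p = 9.54e-05) at GD18 and by −2.33 (SE 0.39, adjusted p = 1.93e-05) at GD19. Of 24 tested members of the list for sarcomere and contractile apparatus, 11 were lower and 2 higher at GD18, and 13 lower and 0 higher at GD19. Counts adjusted over the list alone equalled those over all genes here and below unless both are given. The list mean was 10.03 ± 0.26 (SD) in LE/wt and 9.54 ± 0.11 in LE/orl at GD18, and 10.83 ± 0.28 and 10.19 ± 0.29 at GD19. In the list for muscle energy and calcium handling, 7 of 14 members were lower and 2 higher at GD18, and 8 lower and 1 higher at GD19. Among all 2821 named genes, 1198 were lower and 955 higher at GD18, and 1225 and 921 at GD19. Camera did not call the sarcomere list (adjusted p = 0.419 and 0.369) or the muscle energy list (adjusted p = 0.388 and 0.345). At GD18 Sln was at −2.65 (SE 0.39, adjusted p = 2.77e-06), Cox6a2, the muscle subunit of cytochrome c oxidase, at −2.18 (SE 0.35), and muscle enolase Eno3 at −1.77 (SE 0.30). Of 5 myogenic regulators, 3 were higher at GD18, with Mef2c at 1.47 (SE 0.25, adjusted p = 2.54e-05). All 4 tested smooth muscle genes were lower on both days, and Acta2, smooth muscle actin, differed by −2.19 (SE 0.24) and −1.97 (SE 0.24). GD18 replicate A and GD19 replicate D, whose index was close to LE/wt, were set against LE/wt replicates A and B of both days. The other 6 arrays were set against LE/wt replicates C and D. The median difference of the muscle lists was −0.98 and −0.435, and −0.64 for both together, against −0.58 in the other 6. Each single value also carries the difference between the days. On its own day, the sarcomere mean of GD18 replicate A was 9.70, within the LE/wt arrays. That of GD19 replicate D was 10.12, below all of them. Their muscle energy means of 7.265 and 8.12 lay below every LE/wt array of the day.

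Among 24 genes of mitochondrial oxidative phosphorylation, 18 were lower and 4 higher at GD18, and 17 lower and 3 higher at GD19. Cox4i1 differed by −3.30 (SE 0.43, adjusted p = 4.58e-07) and −3.21 (SE 0.43, adjusted p = 6.6e-07), and Atp5mc1 by −2.87 (SE 0.32) and −2.44 (SE 0.32). The median difference of this list was −1.10 in the 6 arrays with the weak 5′ signal and −0.40 in the other 2. Of 15 genes of Wnt, Bmp, Fgf, Notch and hedgehog signalling, 7 were higher and 4 lower on each day, with Sfrp2 at 2.71 (SE 0.24, adjusted p = 1.21e-09) at GD18 and Notch2 at 1.96 (SE 0.25, adjusted p = 3.37e-07) at GD19. Bmp7, a secreted growth factor, was lower at −1.75 (SE 0.18) at GD18. In the extracellular matrix list of 23, 11 were higher and 6 lower at GD18, and 9 higher and 5 lower at GD19. The collagen chain Col1a2 was at 1.15 (SE 0.13) at GD18, while Timp2, an inhibitor of matrix proteases, was at −1.88 (SE 0.23) on both days. At GD19 the median of the matrix list was 0.15 and its mean −0.001. Of 12 cytoskeletal genes, 4 were higher and 5 lower at GD18 (5 and 5 adjusted over the list alone), and 3 higher and 5 lower at GD19 (5 and 5 adjusted over the list alone). Their median at GD19 was 0.23 and their mean −0.002. Of 9 genes of hormone response and patterning, 3 were higher and 2 lower at GD18, and 1 and 2 at GD19. This list's median and mean were −0.06 and −0.19 at GD18 although its test pointed upward. Ramp1, a subunit of the receptor for calcitonin gene-related peptide, was lower at −1.72 (SE 0.33, adjusted p = 0.000102) and −1.93 (SE 0.33, adjusted p = 2.59e-05). Of 9 cell cycle genes, 4 were lower and 2 higher at GD18 and 5 lower and 1 higher at GD19, and Tk1, a thymidine kinase of S phase, differed by −4.48 (SE 0.32) and −4.97 (SE 0.32).

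Markers of other cell types also moved with strain. Lyve1 of lymphatic vessels was higher by 2.41 (SE 0.36, adjusted p = 4.34e-06) at GD18, and the endothelial cadherin Cdh5 lower at −1.31 (SE 0.38, adjusted p = 0.00542). Of 4 tested endothelial genes, 1 was higher and 3 lower on each day. The macrophage complement gene C1qc was lower at −4.23 (SE 0.65), and the neuronal Uchl1 by −3.65 (SE 0.44). In limma, 4428 of 8711 features were called at GD18, 2333 higher and 2095 lower in LE/orl, and 4534 at GD19, 2282 higher and 2252 lower. No list was called by camera on either day, although with the mean of all probe sets of a gene the oxidative phosphorylation list was at GD19 (adjusted p = 0.0417). At an unadjusted p under 0.05 there was 1 list each day, oxidative phosphorylation, with adjusted p = 0.0904 and 0.0632, and with an estimated correlation there was none. With the 5′ to 3′ index as a covariate, an alternative chosen after seeing the data, 2636 and 2783 features were called. At GD19 the index did not overlap between the strains, and at GD18 only LE/orl replicate A lay within the LE/wt arrays. The covariate and the strain thus compete for the same difference on these days too.

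At GD20, LE/orl gubernacula of both sides had higher Wnt4 and Bmp4, secreted signals of mesenchyme and epithelium, and lower Tnnt3, the fast troponin T, and Myog, the transcription factor myogenin. On the left the Notch ligand Jag1 was higher as well. The patterning gene Hoxa11 was lower on both sides. Every LE/orl array of GD20 had the weak 5′ signal. In LE/orl GD18 replicate A and GD19 replicate D, without it, Hoxa11 was called higher, at 1.37. It was at −1.23 in the other LE/orl arrays of those days. Wnt4 was at −0.71 against 1.40 and Jag1 at −1.28 against 2.16, the first values not called. Tnnt3 was at 0.05 against −1.355, Myog at −0.03 against −0.28 and Bmp4 at −1.46 against −0.52. The weak 5′ signal and the strain thus cannot be told apart for these genes at GD20. Slc3a1 was the named gene with the highest fold change on each side at GD20. It was higher in both sets of earlier LE/orl arrays too, at 4.42 without the weak 5′ signal and 7.86 with it.

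Wnt4 was at 3.19 (SE 0.44, adjusted p = 7.16e-06) on the left with n = 4 per strain and at 3.25 (SE 0.51, adjusted p = 7.5e-05) on the right with n = 3. Its level in left LE/wt gubernaculum was 11.37 ± 0.26 at GD18 and 8.24 ± 0.32 at GD20, whereas LE/orl had 11.98 ± 1.57 and 11.43 ± 0.35. In LE/orl at GD18, replicate A was far from the others at 9.645. Bmp4 was at 1.86 (SE 0.26) and 1.67 (SE 0.31). Of the 15 signalling genes, 10 were higher and 1 lower on the left, and 7 higher and 1 lower on the right (8 and 1 adjusted over the list alone). The signalling list was called upward by camera (adjusted p = 0.0023 left and 0.0122 right; adjusted p = 0.0641 and 0.149 with an estimated correlation). The matrix list, with 9 higher and 4 lower on the left (10 and 4 adjusted over the list alone) and 6 and 3 on the right, was called upward too (adjusted p = 0.0367 and 0.0327; adjusted p = 0.662 and 0.608 with an estimated correlation). Timp3, an inhibitor of metalloproteases, was at 1.68 (SE 0.27) and Loxl1, a crosslinker of elastin, at 1.28 (SE 0.24) on the left. Of the oxidative phosphorylation genes 16 were lower and 0 higher on the left, and 13 lower and 0 higher on the right (15 and 0 adjusted over the list alone). Camera called this list downward (adjusted p = 0.0268 and 0.0154; adjusted p = 0.662 and 0.608 with an estimated correlation), and all LE/orl arrays at GD20 had the weak 5′ signal.

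Of the sarcomere genes 11 were lower on the left and 0 higher (1 higher adjusted over the list alone), and 12 lower and 0 higher on the right. Camera called this list on neither side (adjusted p = 0.405 and 0.1085; adjusted p = 0.944 and 0.703 with an estimated correlation). With the mean of all probe sets of a gene and the preset correlation it did on the right (adjusted p = 0.0479). Tnnt3 was at −2.28 (SE 0.37, adjusted p = 3.22e-05) on the left and −2.14 (SE 0.42, adjusted p = 0.000532) on the right. Of the muscle energy genes 5 were lower and 2 higher on the left and 5 and 1 on the right, with muscle phosphoglycerate mutase Pgam2 at −1.95 (SE 0.40) and −2.09 respectively. The myogenic list had 3 lower on the left and 2 on the right, and 0 higher. Myog differed by −1.42 (SE 0.28, adjusted p = 0.000226) and −1.65 (SE 0.32, adjusted p = 0.000508). Of the smooth muscle genes 3 and 2 were lower. Hoxa11 differed by −2.12 (SE 0.44, adjusted p = 0.000388) and −2.35 (SE 0.51, adjusted p = 0.00109). The hormone response list had 3 higher and 3 lower on the left and 1 and 3 on the right (2 and 3 adjusted over the list alone). Cytoskeletal genes numbered 1 higher and 3 lower on the left and 1 and 4 on the right, and cell cycle genes 2 and 2 on the left and 2 and 1 on the right. The cell cycle list had a median of 0.03 and a mean of −0.36 on the left, with the same signs on the right, and the hormone response list a median and mean below zero on both sides with an upward direction in the set test, which called neither list. In limma, 4046 features were called on the left, 1731 higher and 2315 lower, and 3285 on the right, 1558 higher and 1727 lower. Among the 2821 named genes, from which all list members come, 563 were higher and 1217 lower on the left and 520 and 1022 on the right. The excess of lower calls on the left was not seen with quantile normalisation, at 2008 higher and 1996 lower. With the index as a covariate, which differed between the strains without overlap at GD20, 44 and 40 features were called. With array weights the right side gave 5180. Among markers of other cell types, Uchl1 was lower at −2.10 (SE 0.44) on the left and −1.95 (SE 0.51) on the right and Lyve1 higher at 2.10 (SE 0.36) and 1.98 (SE 0.42). Cdh5 was higher on the left at 1.02 (SE 0.38, adjusted p = 0.0302), opposite to GD18 and GD19.

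**Figure D2:**
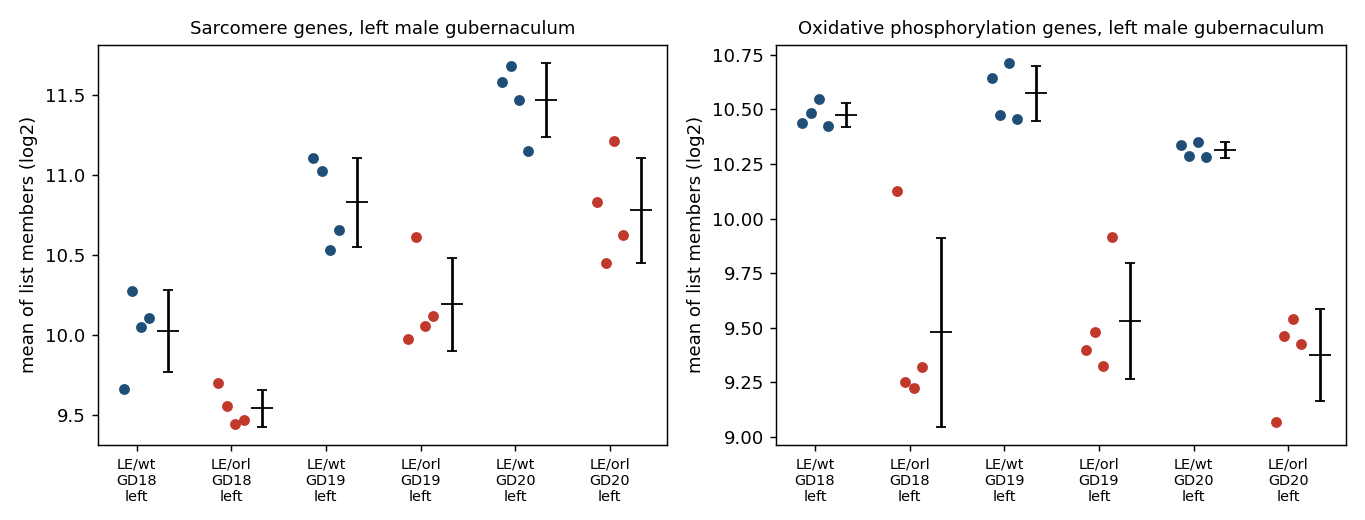
Each point is 1 left male gubernaculum array, plotted by day and strain, with bars for the group mean ± SD of the mean log2 value over the tested members of the sarcomere list (left panel) and the oxidative phosphorylation list (right panel). The sarcomere mean was 10.03 ± 0.26, 10.83 ± 0.28 and 11.47 ± 0.23 in LE/wt at GD18, GD19 and GD20 and 9.54 ± 0.11, 10.19 ± 0.29 and 10.78 ± 0.33 in LE/orl, and the oxidative phosphorylation mean was 10.47 ± 0.06 in LE/wt and 9.48 ± 0.43 in LE/orl at GD18, with every LE/orl array of the 3 days below every LE/wt array.

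Averaged over the 3 left days (n = 12 per strain), the genes with the lowest values in LE/orl were Tk1, Id3, an inhibitor of basic helix-loop-helix factors, and the selenoproteins Selenow and Selenom. Slc3a1 and Ptprj, a receptor tyrosine phosphatase, were the highest. Cpt1a, which brings long-chain fatty acids into mitochondria, was higher, and Cyba, a subunit of NADPH oxidase, lower. Slc3a1 was at 6.72 (SE 0.41, adjusted p = 1.06e-13) and Ptprj at 3.64 (SE 0.19, adjusted p = 7.07e-15). Tk1 was at −4.61 (SE 0.19, adjusted p = 3.42e-17), Id3 at −4.49 (SE 0.43) and Selenow at −4.32 (SE 0.31). Of the sarcomere genes 16 were lower and 1 higher, and of the muscle energy genes 9 lower and 2 higher (9 and 3 adjusted over the list alone). The desmin gene Des, with 0 of the 4 smooth muscle genes higher and 4 lower, was at −1.67 (SE 0.20, adjusted p = 3.04e-08). Myogenic genes were split, 2 higher and 2 lower (3 and 2 adjusted over the list alone). Oxidative phosphorylation had 20 lower and 3 higher and was the 1 list called by camera (adjusted p = 0.0304; adjusted p = 0.789 with an estimated correlation). Signalling genes were 10 higher and 3 lower, matrix genes 12 and 5, hormone response genes 4 and 3, cell cycle genes 2 and 5, and cytoskeletal genes 4 and 6 (5 and 6 adjusted over the list alone), the last with a median of −0.14 and a mean of 0.01. Sfrp2 was at 2.00 (SE 0.14), and the small proteoglycan Ogn at −2.00 (SE 0.19). The fit called 5946 features, 3016 higher and 2930 lower, among them 1014 and 1416 named genes, and 1812 with the 5′ to 3′ index as a covariate.

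Whether the strain difference changed over the 3 days was asked directly. Bmp4 went from lower to higher in LE/orl between GD18 and GD20, and the muscle factors Mef2c and Klhl41 from higher toward lower. Nus1, a subunit of the enzyme that makes dolichol, and Trim33, a ubiquitin ligase, had the lowest p-values, along with Bmyc, a relative of Myc. The GD20 difference minus the GD18 difference was 2.70 for Bmp4 (adjusted p = 6.23e-06), −1.64 for Mef2c (adjusted p = 0.00332) and −1.74 for Klhl41 (adjusted p = 6.84e-05). Bmp4 averaged 8.31 ± 0.33 in LE/wt and 7.46 ± 0.57 in LE/orl at GD18, and 5.81 ± 0.28 and 7.67 ± 0.47 at GD20. For Nus1 the change was −3.88 (adjusted p = 4.72e-10), and its level was 5.97 ± 0.39 in LE/wt males at GD18 against 9.76 ± 0.18 in LE/wt females of that day. Bmyc changed by 3.19 (adjusted p = 8.19e-08) and had 7.26 ± 0.57 in those males against 3.98 ± 0.23 in females. The test called 4 of 5 myogenic genes, 3 of 24 sarcomere genes, 5 of 14 muscle energy genes, 1 smooth muscle gene, 5 cytoskeletal genes, 0 of 9 hormone response genes, 4 matrix genes, 7 of 15 signalling genes (8 adjusted over the list alone), 3 cell cycle genes (6 adjusted over the list alone) and 8 oxidative phosphorylation genes (9 adjusted over the list alone). In limma's F test 2306 of 8711 features were called.

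The sex comparison at GD18 set male left gubernacula of LE/wt against female gubernacula of LE/wt (n = 4 each), since the female gubernaculum does not bring the gonad down. Of 9 cell cycle genes 7 were higher in males, a list that camera called with the preset but not with an estimated correlation. Among them were Cdc20, an activator of the anaphase-promoting complex, the mitotic checkpoint kinase gene Bub1b and Cks2. The transcriptional coactivator Cited1 and the protease inhibitor Timp1 were higher in males as well. Spry1 and Sfrp2 were lower in males, as was Wt1, a transcription factor of urogenital mesenchyme. The muscle transcription factor Myf6 was higher in males.

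Cited1 was at 4.14 (SE 0.37, adjusted p = 6.27e-10), with levels of 8.27 ± 0.26 in males and 4.12 ± 0.14 in females. Aftph, a protein of vesicle traffic, was at −5.80 (SE 0.54), the actin bundler Pls3 at −4.31 (SE 0.45), and septin 7, whose symbol stands as a date in the deposited list, at −4.63 (SE 0.64). Of the cell cycle genes 7 were higher and 1 lower (8 and 1 adjusted over the list alone), with Cdc20 at 1.75 (SE 0.19, adjusted p = 1.7e-08), Cks2 at 2.07 (SE 0.24) and Bub1b at 2.40 (SE 0.34). This was the 1 list called by camera (adjusted p = 0.0158; adjusted p = 0.235 with an estimated correlation). Sarcomere genes numbered 7 higher and 2 lower, muscle energy genes 7 and 3, myogenic genes 1 and 2, smooth muscle genes 3 and 0, and cytoskeletal genes 7 and 4. The slow troponin I gene Tnni1 was at 2.06 (SE 0.32, adjusted p = 3.91e-06), Acta2 at 2.54 (SE 0.24, adjusted p = 2.13e-09) and Myf6 at 2.31 (SE 0.35). Signalling genes were 6 higher and 5 lower (7 and 5 adjusted over the list alone), with Spry1 at −2.68 (SE 0.18) and Sfrp2 at −2.83 (SE 0.24). Matrix genes were 8 and 6, with Timp1 at 2.36 (SE 0.21), oxidative phosphorylation genes 9 and 4, and hormone response genes 2 and 3, with Wt1 at −1.16 (SE 0.18) and the nuclear receptor Nr2f2 at 1.19 (SE 0.33, adjusted p = 0.00345). The fit called 4628 features, 2074 higher and 2554 lower in males, or 2345 and 2305 with array median centring. Markers of other cell types moved as well, with Uchl1 at 2.79 (SE 0.44), Cdh5 at 2.10 (SE 0.38), Lyve1 at −2.00 (SE 0.36), Scd at −2.12 (SE 0.34) and Lpl at −0.82 (SE 0.18). With no minimum signal 9505 were called, 69.8% of them higher in males against 44.8% with it, and of 6993 features under the minimum 4511 were called higher in males, whose poly-A spike means of 8.01 to 8.50 lay below those of females at 9.11 to 10.48.

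Between GD18 and GD20, LE/wt gubernaculum gained transcripts of striated muscle, including the giant sarcomere protein Ttn, the M-band protein Myom1, muscle creatine kinase Ckm and the calcium release channel Ryr1. Chrna1, a subunit of the muscle acetylcholine receptor, rose as well, as did the lipid enzymes Lpl and Scd. Embryonic globin Hbe1, Wnt4, Bmp4 and Cdc20 fell. In LE/orl, too, Ckm and Chrna1 rose, together with the calcium store proteins Casq2 and Hrc.

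In LE/wt, Ttn rose by 3.43 (SE 0.41, adjusted p = 1.52e-07), Myom1 by 2.47 (SE 0.25), Ckm by 3.00 (SE 0.33, adjusted p = 5e-08) and Ryr1 by 2.82 (SE 0.37). Of 24 sarcomere genes 19 rose and 0 fell, of 14 muscle energy genes 9 rose and 1 fell, and all 5 myogenic genes rose, with Mef2c at 2.40 (SE 0.25). Camera called these 3 lists (adjusted p = 7.08e-05, 0.0170 and 0.00139; adjusted p = 0.446, 0.486 and 0.189 with an estimated correlation). Chrna1, the 1 tested gene of the neuromuscular junction list, rose by 1.48 (SE 0.25, adjusted p = 2.52e-05). Of the signalling genes 6 rose and 8 fell, with Spry1 at 2.27 (SE 0.18), Bmp4 at −2.50 (SE 0.26) and Wnt4 at −3.12 (SE 0.44). Of the matrix genes 13 rose and 4 fell, of the cytoskeletal genes 7 and 2, of the hormone response genes 2 and 2, of the smooth muscle genes 0 and 1, of the cell cycle genes 1 and 6, and of the oxidative phosphorylation genes 6 and 8. Hbe1, the 1 erythroid gene tested, was at −3.94 (SE 0.84, adjusted p = 0.000408), and Lpl and Scd, the adipocyte genes tested, at 1.62 (SE 0.18) and 3.70 (SE 0.34). The nerve growth factor receptor Ngfr was at 1.11, Uchl1 at −2.57, Cdh5 at −2.54 and C1qc at −2.94. The fit called 3867 features, 2114 higher and 1753 lower at GD20. The sex difference at GD18 and the difference of GD20 minus GD19 in LE/wt, which share no array, correlated at r = −0.751 across the 8711 tested features, which are not independent replicates.

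In LE/orl 550 features were called, 324 higher and 226 lower, and 131 when only the groups compared were fitted. Casq2 was at 1.95 (SE 0.26, adjusted p = 2.29e-05), Hrc at 2.00 (SE 0.27, adjusted p = 3.06e-05), Ckm at 1.97 (SE 0.33) and Chrna1 at 1.46 (SE 0.25, adjusted p = 0.000574). Of the sarcomere genes 18 rose and 0 fell (21 and 0 adjusted over the list alone), and of the muscle energy genes 13 and 0. Myogenic genes had 2 risen and 0 fallen (4 and 0 adjusted over the list alone), cytoskeletal genes 4 and 0 (4 and 1 adjusted over the list alone) and matrix genes 5 and 0 (9 and 0 adjusted over the list alone). The collagen Col14a1 was at 1.06 (SE 0.17) and the laminin chain Lama2 at 1.16 (SE 0.25). Camera called these 5 lists upward, and all 5 held (adjusted p = 0.0191, 0.0101, 0.0305, 0.0305 and 0.0305 with an estimated correlation). Of the other lists, smooth muscle had 1 risen, hormone response 1 (1 risen and 1 fallen adjusted over the list alone), signalling 1 risen (2 risen and 1 fallen adjusted over the list alone), and cell cycle and oxidative phosphorylation 0. Among markers of other cell types, Hbe1 was at −3.23 (SE 0.84, adjusted p = 0.0175), Lpl at 0.88 (SE 0.18) and Scd, with overlapping groups, at 1.44 (SE 0.34), and Car1 of red cells fell to under the minimum signal. Pla1a, a phospholipase, rose in both strains from levels under the minimum signal at GD18 to 6.93 ± 0.43 in LE/orl and 7.77 ± 0.44 in LE/wt. Left and right gubernacula at GD20, with 8 left and 6 right arrays, gave 0 calls in limma, with 142 features at an unadjusted p under 0.05, 0 calls with the fetus as a fixed or a random block, 3 with array weights, 1 without LE/orl left replicate C, and 0 lists called by camera with 0 at an unadjusted p under 0.05.

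In testis the same strain question was asked at GD17 and GD19. At GD17, LE/orl testes had lower transcripts of the extracellular matrix, led by Col14a1, Lama2 and the collagen VI chain Col6a3. Of 6 Leydig cell genes 3 were lower at GD17 and 4 at GD19, with Lhcgr, the luteinizing hormone receptor, and Prlr, the prolactin receptor, in front, and the list was not called on either day with an estimated correlation. Egfr, the receptor of epidermal growth factor, was lower and Zp2, a coat protein of oocytes, higher. Slc3a1, at low signal, was higher in LE/orl testis as in gubernaculum.

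Of 23 matrix genes 19 were lower and 0 higher at GD17 (20 and 0 adjusted over the list alone). Col14a1 was at −2.03 (SE 0.17, adjusted p = 6.21e-08), Lama2 at −1.68 (SE 0.15, adjusted p = 2.07e-07) and Col6a3 at −1.27 (SE 0.12). The list mean was 8.71 ± 0.18 in LE/wt and 7.91 ± 0.13 in LE/orl at GD17, and 9.29 ± 0.06 and 9.23 ± 0.07 at GD19, when 1 member was higher and 2 lower (2 and 4 adjusted over the list alone). Camera called it at GD17 (adjusted p = 6.96e-17; adjusted p = 0.0115 with an estimated correlation). Of the Leydig genes 6 were lower at GD19 adjusted over the list alone. Lhcgr was at −1.08 (SE 0.11, adjusted p = 5.58e-07) at GD17 and −0.79 (SE 0.11, adjusted p = 3.97e-05) at GD19, with levels of 8.42 ± 0.23 and 9.74 ± 0.10 in LE/wt and 7.34 ± 0.22 and 8.95 ± 0.08 in LE/orl. Prlr was at −1.41 (SE 0.17) and −0.98 (SE 0.17), and the lipoprotein receptor Scarb1 at −0.65 (SE 0.11, adjusted p = 0.000556) at GD19. Camera called the Leydig list on both days (adjusted p = 0.0117 and 0.000170; adjusted p = 0.169 and 0.0897 with an estimated correlation). The Sertoli list had 1 of 3 lower at GD17, the calcium-binding Tesc at −1.75 (SE 0.11, adjusted p = 1.48e-09), and 0 at GD19. Of 8 cholesterol genes 1 was higher at GD17 (0 adjusted over the list alone) and 1 lower at GD19, the sterol reductase gene Tm7sf2 at −0.79 (SE 0.13, adjusted p = 0.000397).

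Averaged over both days (n = 10 per strain), Tnrc6a, a partner of Argonaute proteins, was at −3.13 (SE 0.15, adjusted p = 4.53e-12), Egfr at −1.55 (SE 0.09, adjusted p = 2.02e-10) and Igfbp5, a binding protein of insulin-like growth factors, at −1.52. Zp2 was at 2.91 (SE 0.33, adjusted p = 2.36e-06), Slc3a1 at 2.03 (SE 0.09, adjusted p = 3.19e-12) and Cdkn1c, an inhibitor of the cell cycle, at 0.69 (SE 0.09). Matrix genes were 1 higher and 20 lower (adjusted p = 1.93e-09; adjusted p = 0.0515 with an estimated correlation), and Leydig genes 0 and 4 (0 and 5 adjusted over the list alone; adjusted p = 0.000131; adjusted p = 0.0515 with an estimated correlation). Dnd1, the 1 tested member of the germ cell list, was at 0.35 with overlapping groups. Tk1, the 1 of 9 cell cycle genes called in the mean and at each day, was at −0.48 (SE 0.10) at GD17 and −1.02 (SE 0.10) at GD19. Oxidative phosphorylation had 2 higher and 1 lower at GD17 and 0 and 4 at GD19 (0 and 5 adjusted over the list alone), signalling 2 and 3 (3 and 5 adjusted over the list alone) and 0 and 0, cytoskeleton 0 and 4 and 0 and 1, and hormone response 2 and 1 and 1 and 0 (3 and 1 adjusted over the list alone). Smooth muscle had 0 higher and 2 lower at GD17 and 0 and 1 at GD19, sarcomere 1 and 1 at each, and muscle energy 0 and 2 at each. The cells that express the genes of the lists for other cell types were not tested in testis. Among these genes, Uchl1 was at 0.45 (SE 0.09) at GD17 and 0.43 (SE 0.09) at GD19, Cdh5, with overlapping groups, at −0.59 at GD17, and Scd at −0.95 (SE 0.14) at GD19. In limma 1426 of 7878 features were called at GD17, 563 higher and 863 lower, 1050 at GD19, 415 higher and 635 lower, and 1637 in the mean, 632 higher and 1005 lower. With array median centring the calls were 707 higher and 777 lower at GD17, 515 and 512 at GD19 and 863 and 856 in the mean, so the excess of lower calls depended on the scaling. Of the 2564 named genes 210 were higher and 323 lower at GD17, and 137 and 279 at GD19. The 5′ to 3′ index was −1.09 ± 0.07 in LE/orl and −1.32 ± 0.12 in LE/wt at GD17 (n = 5 each, exact permutation p = 0.008, two-sided, the smallest that this design can give). With the index as a covariate, which differed between the strains without overlap at GD17, that day gave 634 calls, with 19 of the 23 matrix genes lower. In the average of both days the sarcomere, cell cycle, oxidative phosphorylation and cholesterol lists had medians above zero and means below it.

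The testis strain difference changed between the days for matrix genes, of which 19 of 23 had a difference that moved upward from GD17 to GD19 (21 up and 1 down adjusted over the list alone). Fibrillin Fbn1 and Col14a1 were among them. Dusp6, a phosphatase of the MAP kinase ERK, moved the other way, and Tesc, with the immediate early gene Egr1, moved upward. The GD19 difference minus the GD17 difference was 1.63 for Col14a1 (SE 0.24, adjusted p = 0.000546), 1.04 for Fbn1 (SE 0.13, adjusted p = 0.000102), −1.55 for Dusp6 (SE 0.15, adjusted p = 5.52e-06), 1.49 for Tesc (SE 0.16, adjusted p = 1.12e-05) and 1.23 for Egr1 (SE 0.15). Dusp6 averaged 7.55 ± 0.16 in LE/orl and 5.93 ± 0.21 in LE/wt at GD17, and 7.01 ± 0.11 and 6.93 ± 0.20 at GD19. Camera called the matrix list (adjusted p = 3.19e-14; adjusted p = 0.0233 with an estimated correlation). It also called cytoskeleton, 3 of 8 upward (adjusted p = 0.0293; adjusted p = 0.0558 with an estimated correlation), and oxidative phosphorylation, 4 of 24 downward (adjusted p = 0.0349; adjusted p = 0.289 with an estimated correlation). Signalling had 2 upward and 1 downward (2 and 2 adjusted over the list alone), Sertoli 1 upward, and Leydig 0 of 6. In limma 743 features were called, 376 upward and 367 downward, 1142 with array weights and 92 with the 5′ to 3′ index as a covariate, where 5 of the 23 matrix genes were called. The median change of the matrix genes was 0.69 with the index and 0.65 without it, with a median SE of 0.207 and 0.169.

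From GD17 to GD19 most tested matrix genes rose in both strains and embryonic globin fell. Of 6 Leydig cell genes 4 rose in LE/wt and 3 in LE/orl, where 1 fell. With an estimated correlation camera called the matrix list in LE/orl but not in LE/wt, and the Leydig list in neither. Scarb1, Lhcgr and Prlr rose in both, as did Dcn, the proteoglycan decorin, and the smooth muscle gene Tagln. Bub1b and Cks2 fell, and so did Bmp7 and Nppc, the C-type natriuretic peptide. Igfbpl1 and Ndrg4 were among the genes with the highest rise in each strain.

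In LE/wt, Scarb1 rose by 1.87 (SE 0.11, adjusted p = 8.59e-11), Lhcgr by 1.32 (SE 0.11, adjusted p = 6.09e-09) and Prlr by 1.29 (SE 0.17), and in LE/orl by 1.56 (SE 0.11), 1.61 (SE 0.11, adjusted p = 1.35e-10) and 1.72 (SE 0.17). Adjusted over the list alone 3 Leydig genes rose and 2 fell in LE/orl. Camera called the list in both (adjusted p = 0.00312 and 0.0470; adjusted p = 0.102 and 0.267 with an estimated correlation). Of 23 matrix genes 19 rose in LE/wt (adjusted p = 1.82e-07; adjusted p = 0.0998 with an estimated correlation) and 21 in LE/orl (22 adjusted over the list alone; adjusted p = 1.32e-13; adjusted p = 0.0199 with an estimated correlation). Dcn was at 1.28 (SE 0.12) and 2.10 (SE 0.12), and Lama2 at 2.01 (SE 0.15) and 3.29 (SE 0.15). Of 9 cell cycle genes 6 fell in LE/wt (7 adjusted over the list alone) and 7 in LE/orl, with Bub1b at −0.92 (SE 0.08) and −0.87, and the list was called downward (adjusted p = 0.00582 and 0.00659; adjusted p = 0.0478 and 0.0199 with an estimated correlation). In LE/orl, cytoskeletal genes were called upward, 6 up and 1 down (adjusted p = 0.0225; adjusted p = 0.0507 with an estimated correlation), and oxidative phosphorylation downward, 1 up and 15 down (1 and 16 adjusted over the list alone; adjusted p = 0.0225; adjusted p = 0.246 with an estimated correlation). In LE/wt these had 2 up and 1 down, and 2 up and 8 down. Tagln was at 1.69 (SE 0.13) and 1.67 (SE 0.13), with 3 of 4 smooth muscle genes up in each strain. Tesc rose by 0.81 (SE 0.11) and 2.30 (SE 0.11), Tm7sf2 by 1.11 (SE 0.13) and 0.53, and Hbe1 was at −2.11 (SE 0.16) and −2.44 (SE 0.16). Of the lists for other cell types, Uchl1 was at 0.81 (SE 0.09) and 0.79 (SE 0.09), and Cdh5 at 0.36 with overlapping groups and 0.81. Signalling genes had 1 up and 1 down in LE/wt and 5 and 3 in LE/orl, and hormone response genes 0 and 2, and 3 and 1. The fit called 3287 features in LE/wt, 1486 up and 1801 down, and 4375 in LE/orl, 1986 up and 2389 down.

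**Figure D3:**
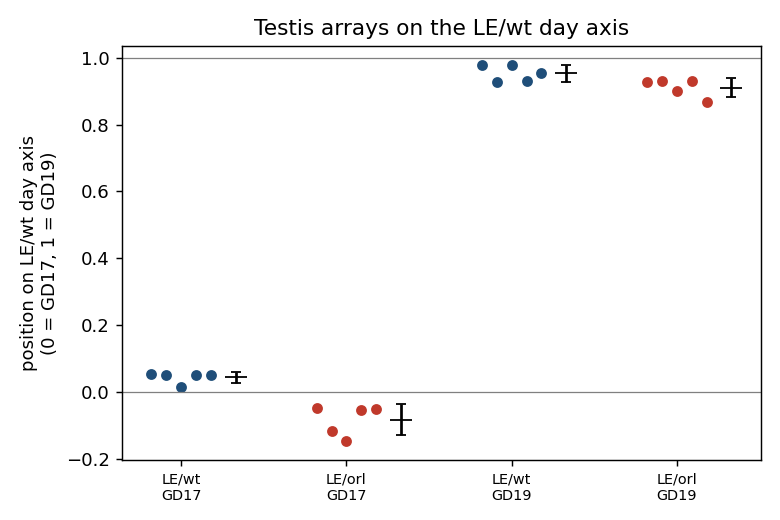
Each point is 1 testis array, placed by its position on axes between means of 4 LE/wt arrays at GD17 (0) and 4 at GD19 (1), leaving out the array itself, with bars for the group mean ± SD (n = 5). LE/orl testes at GD17 lay between −0.147 and −0.047, below the LE/wt testes of that day at 0.015 to 0.052, while both strains at GD19 lay near 1, at means of 0.911 and 0.953.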

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

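The tests of explanations in this part were chosen only after the results had been seen, as were leaving out 2 arrays and the 5′ to 3′ index as a covariate; the tests of the change of the strain difference with day were planned.

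LE/orl gubernacula differed from LE/wt in 4428 features at GD18 and 4534 at GD19, while the median 5′ to 3′ index of 13 of the 15 LE/orl arrays lay apart from that of LE/wt by −2.68. The tables argue against LE/orl GD18 replicate A and GD19 replicate D, whose index is close to LE/wt, being LE/wt tissue under a wrong label: on 26 features that part the strains in testis they scored 0.729 and 0.740, within the other LE/orl arrays at 0.407 to 0.901 and above the LE/wt arrays at −1.02 to −0.178. The difference of these 2 arrays from LE/wt kept a slope of 0.449 on that of the other 6 LE/orl arrays over 5399 features, with 79.0% in the same direction, and slopes of 0.399 and 0.499 for each array alone. The bounds, set after the results were seen, were under 0.25 for the weak 5′ signal as the whole cause and 0.5 or more against it. The slope lies between them, so the weak 5′ signal and the strain cannot be told apart for these features as a whole. For the sarcomere and muscle energy genes the ratio of medians was 1.102 (0.434 to 1.806 over resampled members). The medians were −0.980 and −0.435 in each array alone, against LE/wt arrays of both days. In the 2 arrays 13 of 38 members were called lower and 0 higher, where 3774 of all 8711 features were called. The median of these genes was thus lower in the 2 arrays without the weak 5′ signal too. The sarcomere mean of GD18 replicate A, at 9.70, still lay within the LE/wt arrays of its day. The range of the ratio reaches below 0.5 and leaves out the spread between arrays. The LE/wt arrays behind the 2 medians also differed, with GD19 sarcomere means of 11.11 and 11.02 against 10.53 and 10.66. How much of the muscle difference the weak 5′ signal makes up therefore cannot be told with 2 arrays. For the oxidative phosphorylation genes the ratio was 0.365 (0.022 to 0.919), a range on both sides of these bounds, with 11 of 24 members lower and 5 higher in the 2 arrays. There, too, the weak 5′ signal and the strain cannot be told apart with 2 arrays. A difference between the strains and a batch of the LE/wt arrays stay open for all of these. At GD19 and GD20 the index does not overlap between the strains. With the index as a covariate 2783 features were called at GD19 and 44 at GD20 on the left.

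LE/orl testes at GD17 differed in 1426 features, with 19 of 23 matrix genes and 3 of 6 Leydig cell genes lower. In LE/wt testis 19 and 4 members of these lists rose from GD17 to GD19, although camera with an estimated correlation called neither rise (adjusted p = 0.0998 and 0.102). On the LE/wt course from GD17 to GD19 the LE/orl testes of GD17 lay at a mean position of −0.083, between −0.147 and −0.047, below the LE/wt testes at 0.015 to 0.052 (exact permutation p = 0.00794, two-sided, the smallest possible). At GD19 LE/orl testes lay at 0.911 against 0.953 in LE/wt (exact permutation p = 0.0476, two-sided). Both are consistent with an earlier stage of LE/orl testes. As the whole cause, stage would move nearly all features that change with age toward the earlier day. Of 203 to 362 features called both between the strains at GD17 and between the LE/wt days, with separate LE/wt GD17 arrays in each contrast, a median of 69.7% differed in that direction (63.8% to 73.7% over 10 splits of those arrays), so the tables argue against stage as the whole cause. The shift at GD17 was −0.127 of the course. The mean of the matrix list was lower by 0.803, more than its whole rise of 0.575 from GD17 to GD19 in LE/wt, so a shift of that size at the rate seen between these days does not account for the matrix genes; earlier days were not analysed here. The 5′ to 3′ index of LE/orl testes at GD17 was also higher by 0.231 (exact permutation p = 0.008, two-sided), so a difference in RNA or labelling may contribute. With the index as a covariate 634 features were called, and 19 of the 23 matrix genes were lower with and without it. Their medians were −0.659 (median SE 0.145) and −0.713 (median SE 0.119). The index ran from −1.184 to −0.999 in LE/orl and from −1.452 to −1.191 in LE/wt, without overlap. The covariate and the strain thus compete for the same difference. The matrix difference changed little with the covariate, but this cannot decide whether the index is its whole cause. An earlier stage stays open for the matrix genes only with a faster rise before GD17. Stage and the index stay open as part of the difference in the other features, and the index for the matrix genes as well. A difference between the strains apart from both stays open for all, as untested.

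LE/wt males at GD18 and GD19 stood apart from LE/wt females at GD18 and from LE/wt males at GD20 in the same features, as Nus1 shows with 5.97 ± 0.39 and 6.51 ± 0.54 against 9.76 ± 0.18 and 9.73 ± 0.18. The sex difference and the difference of GD20 minus GD19, which share no array, correlated across tested features at r = −0.751, and across 6993 features under the minimum signal at −0.484 (features are not independent replicates). The second value is consistent with a processing batch shared by the LE/wt male arrays of GD18 and GD19, since features without clear signal should carry little biology, but the labels give no batch. The 2 LE/orl arrays with the stronger 5′ signal differed from LE/wt males at GD19 in that way too, at r = −0.589 under the minimum signal, against −0.275 for the other LE/orl arrays of GD19, and at r = −0.813 across tested features. Sex, age and batch stay open for the sex and LE/wt day differences, and they cannot be separated with these groups. The same LE/wt arrays enter the strain differences at GD18 and GD19 and their change with day, for which a batch stays open as well.

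The strain difference changed with day in 2306 gubernaculum features and 743 testis features by the test of the change itself. In gubernaculum the change rests in part on the LE/wt arrays of GD18, which stood apart in Nus1, and a batch stays open for it. The change from GD18 to GD20 was −3.88 for Nus1, −2.18 for Trim33, 3.19 for Bmyc, −1.85 for C10h5orf15, −2.53 for Dlst and 1.49 for Mrpl52. In testis the change from GD17 to GD19 was −1.55 for Dusp6, 1.49 for Tesc, 1.04 for Fbn1, 1.23 for Egr1, 1.03 for Ahnak and 1.28 for Nek1.

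Single arrays stood far from the rest of their group by Dixon's ratio of the gap to the nearest array over the range of the group. LE/orl GD18 replicate A did so in its 5′ to 3′ index of −4.16, and LE/orl GD19 replicate D in its poly-A spike mean of 9.63. Named genes with such an array numbered 25 in LE/orl at GD18, 14 at GD19 and 18 at GD20 left, 16 in females, and 9, 8 and 7 in LE/wt males at GD18, GD19 and GD20 left. In testis they numbered 6 and 4 in LE/orl at GD17 and GD19, and 6 and 7 in LE/wt. These are 120 of 1442 pairs of gene and group, or 8.32%, and chance gives about 1 in 20 groups. At GD18 in LE/orl the far array was replicate A for all 25 genes.

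Other splits of the same arrays were counted for each comparison. For these the real split was the 1 split with as many calls, a share under 0.05. That is 1 of 35 splits for single gubernaculum comparisons, and 1 of 100 for the mean, the change with day and testis. These are the smallest shares that such numbers of splits can give, and they were not adjusted over the comparisons. They argue against chance as the source of the count but do not exclude it. The real count and the highest of the other splits were 4428 and 2603 at GD18, 4534 and 2198 at GD19, 4046 and 3 at GD20 left, 5946 and 4566 in the mean over left days, 2306 and 1784 for the change with day, 4628 and 517 for sex, 3867 and 1 for the days of LE/wt, and 550 and 70 for those of LE/orl. In testis they were 1426 and 281 at GD17, 1050 and 130 at GD19, 1637 and 931 in the mean, 743 and 487 for the change with day, 3287 and 512 for the days of LE/wt, and 4375 and 1271 for those of LE/orl. In gubernaculum the highest other split exchanged LE/orl replicate A with LE/wt replicate B at GD18, and LE/orl replicate D with LE/wt replicate C at GD19. The LE/orl arrays with the weak 5′ signal thus stayed together in both. For GD20 right, 10 splits are too few for a share under 0.05, with 3285 in the real split and 0 as the highest other. Left against right gave 0 calls in the real split and up to 3 in others. With a real count of 0 all 100 of 100 splits give as many whatever the data, so this count says nothing about chance.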

How the results depend on the processing

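Leaving out 2 LE/orl arrays and the 5′ to 3′ index and poly-A spike mean as covariates were tests chosen only after the results had been seen; the other alternatives were planned.

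Counts of called features stayed within 1.5 times of the reported count except under the settings that follow. With no minimum signal the sex comparison gave 9505 calls among 15704 features tested. With array weights GD20 right gave 5180, the testis change with day 1142 and the left to right comparison 3. With only the groups compared the days of LE/orl gave 131 calls, while those of LE/wt gave 5211 and sex 5147, both within 1.5 times. Adding the index as a covariate gave 2636 calls at GD18, 2783 at GD19, 44 at GD20 left, 40 at GD20 right and 1812 in the mean over left days, and in testis 634 at GD17 and 92 for the change with day. At GD19 and GD20, and in testis at GD17, the index parts the strains without overlap, so the covariate and the strain compete for the same difference. At GD18 the strains overlap only through LE/orl replicate A at −4.16 and LE/wt replicate A at −4.23. For the testis change with day, the matrix genes kept a median of 0.69 against 0.65 while their median SE went from 0.169 to 0.207, and called members from 19 to 5. The cause of the other moves was not tested. Without the 2 arrays, and with the poly-A spike mean, all counts stayed within 1.5 times. Without the 2 arrays the counts were 5011, 4932, 4397 and 3801 for the strain at GD18, GD19, GD20 left and GD20 right, 5103 for sex and 503 for the days of LE/orl. With the poly-A spike mean, GD20 left gave 2904 and sex 3687. The balance of directions depended on the scaling: with median centring, higher and lower calls were 2013 and 2077 at GD20 left, 2345 and 2305 for sex, and in testis 707 and 777 at GD17, 515 and 512 at GD19 and 863 and 856 in the mean.

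Leaving out each array gave 3816 to 4799 calls at GD18, 3995 to 4699 at GD19, 3560 to 3900 at GD20 left, 2539 to 2866 at GD20 right, 5777 to 6119 in the mean, 1887 to 2503 for the change with day, 4173 to 4452 for sex, 3394 to 3612 and 409 to 531 for the days of LE/wt and LE/orl, and 0 to 1 for the sides, with 1 without LE/orl left replicate C. In testis it gave 1065 to 1416 at GD17, 810 to 1053 at GD19, 1418 to 1779 in the mean, 498 to 816 for the change with day, and 3008 to 3184 and 4061 to 4258 for the days. None of the 603 calls of named genes was recorded as changing direction under any setting chosen beforehand. For calls of the F test over the gubernaculum days, direction was not compared. All 603 calls were picked for passing the threshold in the same data, so a change of direction was unlikely from the start. They were not checked with the covariates. The number that lost the call was 18 with no minimum signal, 19 with only the groups compared, 6 with array weights, 5 with quantile normalisation, 4 with median centring, 4 with the letter block, 1 with a trended and robust prior, 0 with all probe sets, 0 of 536 with the stricter minimum, and 163 of 7218 over all arrays left out in turn. Without the 2 arrays, 4 of 383 were lost.

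Replicate letters share only a letter outside the sides at GD20: same-letter correlations of deviations ran from −0.427 to 0.267, and in no comparison did every array correlate best with its own letter. With the letter as a block, the counts were 4383 at GD18, 4491 at GD19, 4024 and 3216 at GD20 left and right, 5924 in the mean, 2260 for the change with day, 4582 for sex, 3817 and 521 for the days, and in testis 1407, 1018, 1599, 719, 3273 and 4359 in the order of the ranges just given. For the sides, the fetus as a block gave 0 calls as a fixed and as a random term, with 323 and 451 features at an unadjusted p under 0.05, and left and right deviations of a fetus correlated at 0.189 to 0.548 in LE/orl and −0.35 to 0.354 in LE/wt. Low signal limits the sex comparison, in which the share of calls higher in males was 69.8% with no minimum and 44.8% with it.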

Other observations

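The test of neighbouring genes in this part was chosen only after the results had been seen, and so were the genes named here across both tissues.

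Strain differences of more than 2-fold in both tissues were few, and most pointed the same way. Among 7191 features tested in gubernaculum and testis, 18 were called by 2-fold in both strain means, 16 of them in the same direction. In the strain means, 1855 of 8711 gubernaculum features and 60 of 7878 testis features were called by 2-fold. Independent lists of those sizes would share some features too. Slc3a1 and Zp2 were higher in LE/orl in both tissues, with 6.72 and 2.10 in gubernaculum and 2.03 and 2.91 in testis. Lower in both were Igfbp5 with −2.79 and −1.52, Egfr with −1.79 and −1.55, Ephx2, an epoxide hydrolase, with −1.96 and −2.30, the aldehyde dehydrogenase Aldh2 with −2.42 and −1.05, and Nit1 with −1.85 and −1.03. In the 2 LE/orl gubernaculum arrays with the stronger 5′ signal Slc3a1 was at 4.42 (adjusted p = 6.15e-08), Egfr at −2.27 (adjusted p = 2.28e-06) and Igfbp5 at −3.79 (adjusted p = 2.1e-06), while Ephx2 was at −1.53 (adjusted p = 0.087), Tc2n, also lower in both tissues, at −0.63 (adjusted p = 0.136) and Aldh2 at 0.11 (adjusted p = 0.838), none of them called. At least one of the strain levels lay under the minimum signal for Slc3a1 in both tissues, and both did in testis at GD17, and for Zp2, Igfbp5 and Ephx2 in testis, so the size of those differences is uncertain. Without the fold, 1037 features were called in both, against 1010.8 for independent lists of these sizes, and 455 of them had the same direction. The agreement in direction thus did not hold for the features called in both as a whole.

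Among other genes, Car1, a carbonic anhydrase that is abundant in red cells, was higher in LE/orl testis at GD17 (adjusted p = 1.22e-05, n = 5 each), at 7.68 ± 1.20 against 3.76 ± 1.16, a level under the minimum signal of 5, whereas Hbe1 was at 13.78 ± 0.18 and 13.58 ± 0.14. At GD19 Car1 lay under the minimum in both strains. Cdkn1c fell by 1.19 from GD17 to GD19 in LE/wt testis and was higher in LE/orl at GD19 by 0.90 (SE 0.13, adjusted p = 9.97e-05). In the LE/wt gubernaculum the urokinase gene Plau rose from under the minimum at GD18 to 6.86 at GD20, and Angptl4, an inhibitor of lipoprotein lipase, fell by 2.82 (SE 0.29) while Lpl rose. Pnoc, the precursor of the opioid-like peptide nociceptin, and the purine enzyme gene Xdh were higher in male than in female gubernaculum, by 3.65 (SE 0.47) and 3.88 (SE 0.29).

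Several testis strain genes lie close to each other on the chromosomes of the rat assembly GRCr8. Among 64 genes called in the testis strain mean with a fold of at least 1.6, 12 had another such gene within 10 protein-coding genes, against a median of 4 in 10000 random draws from the 2355 named genes with a place in the assembly (permutation p = 0.0119, one-sided). Crym and Zp2 were next to each other, and Ddc with Egfr, Mgp with Plbd1, Dcn with Dusp6, Lgmn with Tc2n and Ramp1 with Col6a3 were the other pairs. Variants linked between the strains might give such pairs. Over 9 settings of fold and distance 4 had a p under 0.05, from 0.0058 to 0.682, so the hypothesis stays open.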
